A study of Mus musculus with 4 samples.

How the data were processed

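The series measured RNA of the distal colon of DSS-treated mice by sequencing, in 2 wild-type and 2 Elf4fl/fl-Villin-Cre libraries. Groups and replicate numbers were taken from the genotype and title labels. Per the labels, RNA was extracted with Trizol and libraries followed standard Illumina protocols. The strain label of the Elf4fl/fl-Villin-Cre samples reads C57BL/8, while the series design gives C57BL/6 for all mice. Nothing in the labels says whether the replicates were separate animals, whether the genotypes were littermates or what alleles the wild-type mice carried. P-values therefore measure the spread between these samples, which may be partly technical.

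The deposited table gives 1 value per gene and library, a normalised signal made by the authors and not raw counts. Every value in a library was a whole multiple of the library's smallest value above 0. Dividing by that step gave whole reads for 100% of values (tolerance 0.01), so the deposited signal is a read count divided by 1 scaling factor per library, without gene length. One read was worth 1.03 and 1.05 in the wild-type libraries and 0.814 and 0.836 in the Elf4fl/fl-Villin-Cre libraries. The genome build was mm10, per the submitters' processing notes. The aligner, the counter, the annotation release, the strandedness and the tool behind the scaling factors are not given in the sources used here. Symbols and positions came from the GENCODE mouse release 21 annotation of that build, which matched 22376 of the 22422 gene identifiers (99.8%) when version numbers were ignored. The 46 others were kept without a symbol. Reads of near-identical genes, such as gasdermin C, globin, mast cell protease and 2'-5' oligoadenylate synthetase paralogs, and of overlapping antisense genes, may have been split or dropped by the counting, so single members are uncertain.

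The recovered reads came to 16134509 and 15885028 in wild type and 16023926 and 16425954 in Elf4fl/fl-Villin-Cre colon, so depth did not differ by group. The 10 most abundant genes took 10.1% and 9.32% of wild-type reads and 5.64% and 6.71% of Elf4fl/fl-Villin-Cre reads. Clca1, a goblet cell product, alone took 2.99% and 2.31% against 0.612% and 1.27%. Replicates correlated across genes at 0.972 and 0.973 (Pearson r of log2 values), and libraries of different groups at 0.939 to 0.961. The chi-square per degree of freedom between replicates was 24.6 in wild type and 25.3 in Elf4fl/fl-Villin-Cre colon, so replicates differed by more than counting noise. That does not show whether they came from separate animals. For genes at 0 reads in a group, 3 reads over the group were used as the floor, which covers counting error only.

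The planned test for normalised values was used: limma (3.58.1, in R 4.3.3) on log2(value + 1), with a variance trend, genotype as the only term, all 4 libraries, and Benjamini-Hochberg adjustment at 0.05. Genes with a mean value under 1 were left out, which kept 22050. The fit had 2 residual degrees of freedom and 4.06 prior ones. Groups did not overlap for 62.2% of genes, against 33.3% by chance. Because whole reads were recovered, edgeR's quasi-likelihood test (4.0.16, TMM scaling, filterByExpr) was added after seeing the data. It called 4054 of 17337 genes, 1713 higher and 2341 lower, and 3378 genes were called by both tests in the same direction. Its common biological coefficient of variation was 18.7%.

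Gene lists for the cell types and pathways of inflamed colon, 37 in all, were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37. Camera with an estimated correlation called 0 lists (smallest adjusted p = 0.72). That form of the test rests on the 2 residual degrees of freedom, so few lists could pass it whatever their correlation. The enteroendocrine list had an estimated correlation of -0.0142, below the preset value, yet its unadjusted camera p went from 0.00346 to 0.0898. The 0 calls therefore do not decide whether correlation between genes accounts for the calls at the preset value. Fry, which asks whether the genes of a list move on balance one way, called 0 (smallest adjusted p = 0.0727, 15 lists at an unadjusted p under 0.05), and 26 for change in either direction. Some lists share members, such as S100a8 and S100a9 (neutrophil and antimicrobial), Trem1 and Spp1, and several markers are made by more than 1 cell type in colon.

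Named genes followed a rule fixed before the data were examined. It took Elf4, and the 8 largest log2 fold changes in each direction among genes past the adjusted threshold whose groups did not overlap and whose mean lay above the median of tested genes. Predicted genes, pseudogenes and immunoglobulin or T cell receptor segments were left out. In each list it took up to 4 members past the threshold by smallest p, or up to 2 members as values where none passed. Some genes that the rule takes are not reported here. Other genes named to explain a count of 5 or fewer, and those in the closing section, were chosen after their values were seen.

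The scripts were tested on 10 simulated data sets with 200 changed genes each, drawn from the real means and depths. In them limma called 21.1% of genes changed by a fold of 2 and 82.0% of those changed by a fold of 4, with 8.26% of calls false. edgeR called 38.1% and 89.4%, with 14.7% of calls false. A list of 20 raised genes was called in 10 of 10 simulations and an unchanged one in 0. The simulated genes varied independently, so these list results do not carry over to correlated genes. In the real lists the estimated correlation reached 0.96. The simulations also changed far fewer genes than the 3409 called in the data, so the shares of false calls may differ there. Alternatives were another pseudocount, filters, scalings, thresholds, the replicate number as a block, leaving out each library, and, added after seeing the data, DESeq2 (1.42.0), limma-voom, edgeR variants and a fit with GC content and gene length trends removed. Figures were drawn with matplotlib 3.10.9.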

Results

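RNA of the whole distal colon was sequenced from female C57BL/6 mice, 6 weeks old, after 5 days of 2% dextran sulfate sodium (DSS). DSS is a polysaccharide that injures the colonic epithelium and sets off colitis. The mice were wild type or Elf4fl/fl-Villin-Cre, in which Cre recombinase made under the villin promoter deletes the loxP-flanked Elf4 gene in intestinal epithelium. Each genotype had 2 libraries. The deposited table held 22422 genes as normalised read counts. The whole reads behind them came to 16134509 and 15885028 in the wild-type libraries and 16023926 and 16425954 in the Elf4fl/fl-Villin-Cre libraries. Colon without DSS was not analysed here, so the response to DSS itself was not measured. Fold changes are Elf4fl/fl-Villin-Cre over wild type on the log2(value + 1) scale, which understates the change of genes with few reads.

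Elf4, which encodes a transcription factor of the ETS family, was lower in the colon of Elf4fl/fl-Villin-Cre mice. The gene (ENSMUSG00000031103.12, chromosome X, 48411046 to 48463132 in mm10) stood at 1588 and 1938 normalised reads in the wild-type libraries. In the Elf4fl/fl-Villin-Cre libraries it stood at 897 and 758. The means were 1763 ± 248 and 827 ± 99.0 (SD, n = 2 each), a 2.13-fold difference. On the log2 scale Elf4 fell by 1.09 ± 0.16 (SE; limma adjusted p = 0.0139). A count per gene does not show whether the deleted exons were among those read, and the tissue also holds cells in which villin is not made. Epithelial junction genes fell in the same libraries, with a median log2 fold change of -1.29 over 23 genes.

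In Elf4fl/fl-Villin-Cre mice the DSS-treated colon had higher RNA of inflammatory mediators and of neutrophil and macrophage markers. It had lower RNA of absorptive and goblet cell genes, cell junctions, oxidative phosphorylation and type I interferon-stimulated genes. Of 24 inflammatory cytokines, chemokines and proteases, 19 rose, with a median log2 fold change of 3.16 over the list. Of 21 absorptive colonocyte genes, 16 fell, with a median of -1.57. Camera called each of these lists at its preset correlation, but 0 with an estimated one (adjusted p = 0.72 for each). The form with an estimated correlation rests on 2 residual degrees of freedom, too few to decide for or against a list. Fry called 0 of the 37 lists (15 at an unadjusted p under 0.05). Of the 22050 genes tested, 1512 were higher and 1897 lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 904 and 1043 of these differed by a fold of at least 2.

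Among genes that the naming rule admits, those with the largest increases included matrix proteases and cytokines. The matrix metalloproteinases Mmp10 and Mmp13 rose by 5.64 ± 0.42 and 5.23 ± 0.44 (log2 fold change ± SE), with limma adjusted p of 0.00646 and 0.00737. Ptgs2, the inducible cyclooxygenase, went from 255 ± 98.8 to 8790 ± 759 normalised reads (SD, n = 2 each; limma adjusted p = 0.00401). Csf3, which encodes the granulocyte growth factor G-CSF, rose by 5.05 ± 0.55, the acute-phase gene Saa3 by 4.90 ± 0.43 and the interleukin 6 family cytokine Il11 by 4.79 ± 0.44 (limma adjusted p = 0.00942, 0.00742 and 0.00792). Without wild type replicate 2 and without wild type replicate 1, respectively, Csf3 stood at 4.20 and 5.91, Saa3 at 4.23 and 5.56 and Il11 at 4.07 and 5.51. Inhba, the activin A subunit, rose by 4.71 ± 0.16 (limma adjusted p = 0.00114). Chil3, a chitinase-like protein of macrophages and neutrophils, rose by 5.10 ± 0.88 (limma adjusted p = 0.0185). Its Elf4fl/fl-Villin-Cre values lay apart, at 1823 and 318, and edgeR did not call it without wild type replicate 1 or without wild type replicate 2 (highest adjusted p = 0.0879). Without Elf4fl/fl-Villin-Cre replicate 1 and 2, respectively, Mmp13 stood at 5.86 and 4.60 and Chil3 at 3.85 and 6.36.

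Among genes that the naming rule admits, the largest decreases were in gasdermin C genes, mucosal mast cell proteases and transport genes. Gsdmc2, Gsdmc4 and Gsdmc3, neighbouring genes on chromosome 15, fell by 4.47, 4.05 and 3.69 on the log2 scale (limma adjusted p = 0.0089, 0.00965 and 0.00636). These paralogs are alike enough that reads can be shared among them, so the split between them is uncertain. Cma2 had 653 and 148 normalised reads in wild type and 0 and 3.34 in Elf4fl/fl-Villin-Cre colon (limma adjusted p = 0.0109). Mcpt1, a protease of mucosal mast cells, fell by 4.11 ± 0.64 (limma adjusted p = 0.015). Aqp4, a water channel, went from 2756 ± 70.6 to 170 ± 19.5 normalised reads (SD, n = 2 each; limma adjusted p = 0.00114). Slc13a2, a sodium-dependent dicarboxylate transporter, fell by 3.89 ± 0.37. Hao2, a peroxisomal hydroxy acid oxidase, fell by 4.10 ± 0.73 (limma adjusted p = 0.0197), and edgeR did not call it without wild type replicate 2 (adjusted p = 0.0586). Without Elf4fl/fl-Villin-Cre replicate 1 and 2, respectively, the log2 fold change was -3.78 and -5.16 for Gsdmc2, -3.29 and -4.81 for Gsdmc4, -3.32 and -4.89 for Mcpt1, -3.30 and -4.48 for Slc13a2 and -2.89 and -5.30 for Hao2.

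**Figure D1:**
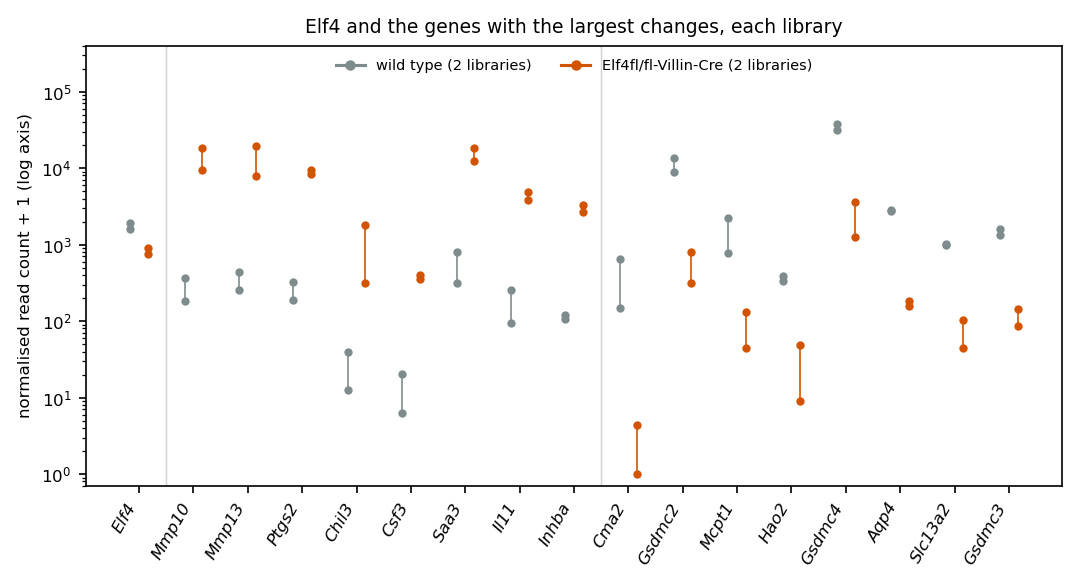
Normalised read counts plus 1, on a log axis, of Elf4 and of the 8 largest increases and 8 largest decreases among genes that the selection rule admits. The rule leaves out genes with a mean at or below the median of tested genes, predicted genes and pseudogenes. Each point is 1 library and a line joins the 2 libraries of a group. Elf4 lies between 758 and 897 in Elf4fl/fl-Villin-Cre colon and between 1588 and 1938 in wild type. For each gene shown the groups do not overlap, which the selection rule required of all but Elf4.

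Epithelial genes were lower for the main cell types of the colonic lining. Among absorptive colonocyte genes, 16 of 21 fell and 0 rose (20 fell when adjusted over the list alone; camera adjusted p = 3.04e-11, and adjusted p = 0.72 with an estimated correlation). The carbonic anhydrase gene Car4, the guanylin gene Guca2a and the microvillus protein gene Vil1 fell by 1.89, 2.42 and 1.58 on the log2 scale (limma adjusted p = 0.00737, 0.00742 and 0.00942). Goblet cell genes fell in 10 of 18 cases and 0 rose (12 fell when adjusted over the list alone; camera adjusted p = 3.82e-07, and adjusted p = 0.72 with an estimated correlation). Fer1l6 fell by 1.10 and Galnt12, which starts mucin-type glycosylation, by 1.42 (limma adjusted p = 0.0141 and 0.0152). Of 23 epithelial junction genes, 17 fell and 1, Cldn4, rose by 0.92 (19 fell and 1 rose when adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.72 with an estimated correlation). The desmosomal gene Dsp fell by 1.87 and the tight junction genes Marveld2 and Cldn7 by 1.59 and 1.29 (limma adjusted p = 0.0115, 0.00959 and 0.0117).

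Enteroendocrine genes moved the other way. Of 14 genes of these hormone-secreting epithelial cells, 4 rose and 0 fell (4 when adjusted over the list alone; 7 rose under library totals), and the median log2 fold change was 0.55 (camera adjusted p = 0.00853, and adjusted p = 0.72 with an estimated correlation). Gcg, which encodes proglucagon, went from 1078 ± 63.1 to 2322 ± 331 normalised reads (SD, n = 2 each; limma adjusted p = 0.0119), and Insl5 rose by 0.96 (limma adjusted p = 0.0202). The list lost its call in edgeR without Elf4fl/fl-Villin-Cre replicate 2 (adjusted p = 0.0634), and Insl5 without wild type replicate 2 (adjusted p = 0.0767). Of the other 2 genes that rose, Tph1 lost its edgeR call without wild type replicate 2 or without Elf4fl/fl-Villin-Cre replicate 1 (highest adjusted p = 0.0838), and Scg5 in each of the 4 fits without 1 library (highest adjusted p = 0.0985). In the tuft cell list 1 of 11 genes fell and 0 rose (1 when adjusted over the list alone; camera adjusted p = 0.528), and under library totals 3 rose and 1 fell.

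Stem cell and repair genes went both ways. In the stem and progenitor list 2 of 16 rose and 4 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.228). Cd44, a hyaluronan receptor also made by leukocytes, rose by 1.73 and the progenitor transcription factor gene Myb fell by 2.28 (limma adjusted p = 0.0072 and 0.0102). In the fetal-like repair list 6 of 16 rose and 1 fell (6 and 1 when adjusted over the list alone; camera adjusted p = 0.109). Camera called that list higher in 13 of 24 other settings, including edgeR with all libraries, quantile scaling and the 4 edgeR fits without 1 library (adjusted p = 1e-04 to 0.00174), but in 0 of the 4 such limma fits (adjusted p = 0.0636 to 0.15). Its largest rise was in Ereg, the EGF receptor ligand epiregulin, which went from 966 ± 417 to 21245 ± 3684 normalised reads (SD, n = 2 each; limma adjusted p = 0.00636). Of the 20 proliferation genes, 0 passed limma over all genes or adjusted over the list alone, and 0 passed edgeR (0 higher and 3 lower at an unadjusted p under 0.05). As a list they were lower by camera (adjusted p = 0.021, and adjusted p = 0.80 with an estimated correlation), but the median of -0.22 turned to 0.09 under library totals. That call was lost in 12 of 24 other settings, including edgeR with all libraries, limma without wild type replicate 1 (adjusted p = 0.386) or without Elf4fl/fl-Villin-Cre replicate 2 (adjusted p = 0.161), and edgeR without Elf4fl/fl-Villin-Cre replicate 1 (adjusted p = 0.0612).

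Metabolic genes fell beside the epithelial lists. Of 19 nuclear genes of oxidative phosphorylation, 15 fell and 0 rose (17 fell when adjusted over the list alone; camera adjusted p = 1.4e-08, and adjusted p = 0.72 with an estimated correlation). Cox5a, of cytochrome c oxidase, fell by 1.36 and Atp5b, of ATP synthase, by 1.27 (limma adjusted p = 0.00942 and 0.0121). Of the 13 genes encoded in the mitochondrial genome, 0 passed limma over all genes or adjusted over the list alone, and 0 passed edgeR (0 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.539). Sterol and lipid genes fell in 12 of 20 cases and rose in 2 (13 and 2 when adjusted over the list alone; camera adjusted p = 0.000118, and adjusted p = 0.72 with an estimated correlation). The cholesterol synthesis gene Sqle fell by 1.40, and Angptl4, which inhibits lipoprotein lipase, rose by 2.45 (limma adjusted p = 0.00942 and 0.00636). Of 20 xenobiotic genes, 6 fell and 2 rose (8 and 2 when adjusted over the list alone; camera adjusted p = 0.0185, and adjusted p = 0.72 with an estimated correlation). Aldh1b1 fell by 1.47 and the glutathione transferase gene Gstm3 by 3.54 (limma adjusted p = 0.00973 and 0.00986), and the list's call was lost in edgeR with a stricter filter (adjusted p = 0.115). With quantile scaling 0 xenobiotic genes rose and 4 fell, and under library totals 4 rose and 4 fell. In these libraries the junction list, which marks epithelium, had a median of -1.29.

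Inflammatory mediators had the largest median of the lists called with all libraries. Of 24 genes, 19 rose and 1, Il18, fell by 2.73, a call that edgeR lost without wild type replicate 2 (adjusted p = 0.0518; 22 rose and 1 fell when adjusted over the list alone; camera adjusted p = 1.56e-09, and adjusted p = 0.72 with an estimated correlation). Il18 stood at -2.05 without Elf4fl/fl-Villin-Cre replicate 1 and -3.40 without Elf4fl/fl-Villin-Cre replicate 2. Il1a went from 27.6 ± 4.69 to 338 ± 27.9 normalised reads (SD, n = 2 each; limma adjusted p = 0.00636). Cxcl5, a neutrophil-attracting chemokine, rose by 1.63 ± 0.13 (limma adjusted p = 0.00737). Of the 17 neutrophil genes, 13 rose and 0 fell, with a median of 2.33 (14 when adjusted over the list alone; camera adjusted p = 3.5e-07, and adjusted p = 0.72 with an estimated correlation). Erythroid genes, which mark blood, had a median of 2.57 in the same libraries, or 1.84 without wild type replicate 1 and 3.39 without wild type replicate 2. Csf3r, the G-CSF receptor, rose by 2.15, and Clec4d and the granule collagenase gene Mmp8 by 3.36 and 4.67 (limma adjusted p = 0.00737, 0.00737 and 0.0089). Of 18 monocyte and macrophage genes, 14 rose and 0 fell, with a median of 0.97 (16 when adjusted over the list alone; 9 rose with median scaling; camera adjusted p = 3.23e-06, and adjusted p = 0.72 with an estimated correlation). Among them Cd14 rose by 1.37, the scavenger receptor gene Cd163 by 1.61 and the mannose receptor gene Mrc1 by 0.91 (limma adjusted p = 0.0089, 0.00986 and 0.0127).

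**Figure D2:**
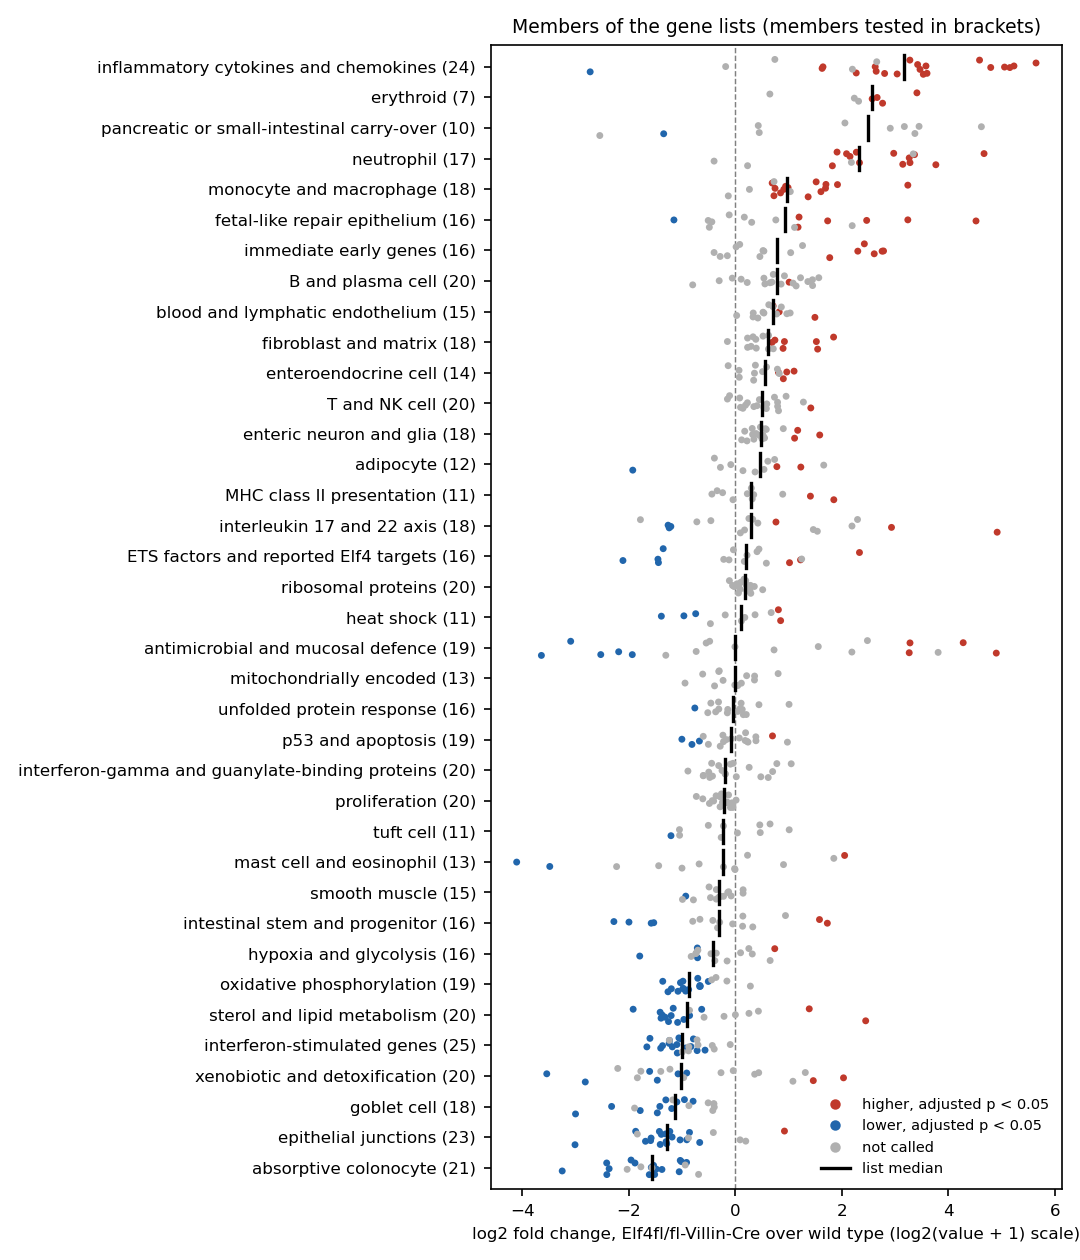
Log2 fold change of each tested member (points) of the 37 gene lists, Elf4fl/fl-Villin-Cre over wild type on the log2(value + 1) scale, with the list median as a black bar and lists ordered by median. The inflammatory list has its median at 3.16 and the absorptive list at -1.57; the smooth muscle, proliferation, tuft, mast cell, interferon-gamma, p53, unfolded protein, mitochondrial and antimicrobial medians, from -0.31 to -0.01, turn to values from 0.01 to 0.31 under library totals.

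Lymphocyte lists had few single genes past the test. In the T and NK cell list 1 of 20 genes, Il7r, passed as higher and 0 as lower (0 when adjusted over the list alone). edgeR called Il7r in only 1 of the 4 fits without 1 library, that without Elf4fl/fl-Villin-Cre replicate 2 (highest adjusted p = 0.126). The list was higher by camera (adjusted p = 0.0293, and adjusted p = 0.80 with an estimated correlation). That call was lost in 12 of 24 other settings, including edgeR with all libraries, and limma without wild type replicate 2 (adjusted p = 0.624) or without Elf4fl/fl-Villin-Cre replicate 1 (adjusted p = 0.206). In the B and plasma cell list 1 of 20, Jchain, passed as higher and 0 as lower (0 when adjusted over the list alone; camera adjusted p = 0.0691). Jchain lost its edgeR call without wild type replicate 2 or without Elf4fl/fl-Villin-Cre replicate 1 (highest adjusted p = 0.129). Camera called that list higher in 14 of 24 other settings, but not without wild type replicate 2 (limma, adjusted p = 0.874) or without Elf4fl/fl-Villin-Cre replicate 1 (limma, adjusted p = 0.266). In the mast cell and eosinophil list Mcpt1 and Mcpt2 fell and Hdc, the histamine-forming enzyme, rose, 2 lower and 1 higher of 13 (2 and 1 when adjusted over the list alone; camera adjusted p = 0.435). Of 11 genes of MHC class II presentation, 2 rose and 0 fell (2 when adjusted over the list alone; camera adjusted p = 0.469), and both, Cd80 and Cd86, encode costimulatory ligands. Neither was called by edgeR without wild type replicate 2 (adjusted p = 0.0596 and 0.0719).

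Interferon-stimulated genes were lower as a group. Of 25, 16 fell and 0 rose, with a median of -0.997 (20 fell when adjusted over the list alone; camera adjusted p = 2.52e-09, and adjusted p = 0.72 with an estimated correlation). The oligoadenylate synthetase genes Oas1a, Oas2 and Oas3 fell by 1.66, 1.37 and 1.61 (limma adjusted p = 0.00942, 0.0103 and 0.0104). Ifih1, which encodes the RNA sensor MDA5, went from 4775 ± 133 to 2228 ± 19.2 normalised reads (SD, n = 2 each; limma adjusted p = 0.00965). In the separate list of 20 interferon-gamma and guanylate-binding protein genes, 0 passed limma over all genes or adjusted over the list alone, and 0 passed edgeR (0 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.323). Camera called that list in 5 of 24 other settings, all with 1 library left out, and the direction turned with the library. It was lower without wild type replicate 2 (limma and edgeR, adjusted p = 0.0283 and 0.0457) or without Elf4fl/fl-Villin-Cre replicate 1 (adjusted p = 0.000189 and 3.13e-06), and higher in edgeR without Elf4fl/fl-Villin-Cre replicate 2 (adjusted p = 0.0218). Its smallest p was that of Irf1, at 7256 ± 321 in wild type and 4050 ± 1505 in Elf4fl/fl-Villin-Cre colon (SD, n = 2 each; limma adjusted p = 0.0706). The epithelial junction median of -1.29 was measured in the same libraries.

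Mucosal defence genes went both ways. Of 19 antimicrobial genes, 4 rose and 5 fell (4 and 8 when adjusted over the list alone; camera adjusted p = 0.424). Saa3, S100a9 and the siderophore-binding protein gene Lcn2 rose by 4.90, 3.26 and 4.28, while Dmbt1, a secreted scavenger receptor of epithelium, fell by 2.19 (limma adjusted p = 0.00742, 0.00953, 0.00973 and 0.0107). Without wild type replicate 2 and without wild type replicate 1, respectively, S100a9 stood at 2.66 and 3.87 and Lcn2 at 3.54 and 5.02. In the interleukin 17 and 22 list 3 of 18 rose and 3 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.539). Il17a had 0 reads in wild type and 43 and 29 in the Elf4fl/fl-Villin-Cre libraries, at least 19.0-fold higher when 3 reads over the wild-type group are taken as the floor (limma adjusted p = 0.00965). Putting Il17a at that bound left the list median at 0.29. The receptor genes Il17rc and Il22ra1 fell by 1.21 and 1.24 (limma adjusted p = 0.00942 and 0.0153).

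The fibroblast, endothelial and enteric neuron lists were higher, and smooth muscle and adipocyte lists were not. Of 18 fibroblast and matrix genes, 7 rose and 0 fell, with a median of 0.62 (9 when adjusted over the list alone; camera adjusted p = 0.000649, and adjusted p = 0.77 with an estimated correlation). Dcn, the matrix proteoglycan decorin, went from 6412 ± 300 to 23002 ± 981 normalised reads, and the BMP antagonist gene Grem1 rose by 1.52 (SD, n = 2 each; limma adjusted p = 0.00742 and 0.00942). Of 15 endothelial genes, 3 rose and 0 fell, with a median of 0.70 (7 when adjusted over the list alone; camera adjusted p = 0.00458, and adjusted p = 0.77 with an estimated correlation). Of 18 enteric neuron and glia genes, 3 rose and 0 fell, with a median of 0.48 (5 when adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.72 with an estimated correlation). Vip, a neuropeptide, and the glial filament gene Gfap rose by 1.58 and 1.11 (limma adjusted p = 0.00825 and 0.0132), and the list missed its call in edgeR without Elf4fl/fl-Villin-Cre replicate 2 (adjusted p = 0.0654). Of 15 smooth muscle genes, 1, Des, passed as lower and 0 as higher (0 when adjusted over the list alone; camera adjusted p = 0.0259, and adjusted p = 0.80 with an estimated correlation). edgeR called Des in only 1 of the 4 fits without 1 library, that without Elf4fl/fl-Villin-Cre replicate 2 (highest adjusted p = 0.124). The list median of -0.31 turned to 0.04 under quantile scaling and 0.01 under library totals. The smooth muscle call was lost in 12 of 24 other settings, including edgeR with all libraries, and limma without wild type replicate 1 (adjusted p = 0.164) or without Elf4fl/fl-Villin-Cre replicate 1 (adjusted p = 0.292). Of 7 erythroid genes, 4 rose and 0 fell, all of them globin genes, with a median of 2.57, or 1.84 without wild type replicate 1 and 3.39 without wild type replicate 2 (6 when adjusted over the list alone; camera adjusted p = 0.00491, and adjusted p = 0.77 with an estimated correlation). Of 12 adipocyte genes, 2 rose and 1 fell (2 and 1 when adjusted over the list alone; camera adjusted p = 0.469).

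Early response genes rose, and most other stress lists had few calls. Of 16 immediate early genes, 6 rose and 0 fell, with a median of 0.79 (11 when adjusted over the list alone; 11 rose under library totals; camera adjusted p = 0.00491, and adjusted p = 0.72 with an estimated correlation). The transcription factor gene Egr1 rose by 2.78 and the phosphatase gene Dusp1 by 1.77 (limma adjusted p = 0.0083 and 0.00636). Of 16 hypoxia and glycolysis genes, 3 fell and 1, Ndrg1, rose (7 and 1 when adjusted over the list alone), and under library totals 3 rose and 1 fell. Ndrg1 lost its edgeR call without wild type replicate 1 or without Elf4fl/fl-Villin-Cre replicate 1 (highest adjusted p = 0.0837). The list was lower by camera (adjusted p = 0.0273, and adjusted p = 0.77 with an estimated correlation), and Car9, a carbonic anhydrase, fell by 1.80 (limma adjusted p = 0.0123). The list's call was lost in 10 of 24 other settings, including edgeR with all libraries, limma without wild type replicate 2 (adjusted p = 0.179) or without Elf4fl/fl-Villin-Cre replicate 2 (adjusted p = 0.0612), and edgeR without Elf4fl/fl-Villin-Cre replicate 1 (adjusted p = 0.0519). In the p53 and apoptosis list 1 of 19 rose and 3 fell (1 and 4 when adjusted over the list alone; camera adjusted p = 0.435), among them the necroptosis gene Mlkl, by 1.01 (limma adjusted p = 0.0194). Under library totals 4 genes of that list rose and 2 fell. In the heat shock list 2 of 11 rose and 3 fell (3 and 4 when adjusted over the list alone; camera adjusted p = 0.641), and under library totals 5 rose and 1 fell. Of 16 unfolded protein response genes, 1, Calr, passed as lower and 0 as higher (1 when adjusted over the list alone; camera adjusted p = 0.403). edgeR called Calr in only 1 of the 4 fits without 1 library, that without Elf4fl/fl-Villin-Cre replicate 2 (highest adjusted p = 0.0889), and under library totals 2 genes of the list rose and 0 fell. Of 20 ribosomal protein genes, 0 passed limma over all genes or adjusted over the list alone, and 0 passed edgeR (1 higher and 0 lower at an unadjusted p under 0.05; camera adjusted p = 0.259).

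Other ETS-family factors and genes reported to be Elf4 targets changed in both directions. Of 16, 3 rose and 4 fell (4 and 4 when adjusted over the list alone; camera adjusted p = 0.832). The list joins ETS-family factors with reported targets and sets no expected direction for its members. Camera tests for a shift 1 way, so its result does not show whether single targets responded. The epithelial factors Elf3, Klf5 and Klf4 fell by 1.45, 2.11 and 1.36, and the myeloid receptor gene Trem1 rose by 2.33 (limma adjusted p = 0.0118, 0.0138, 0.0142 and 0.00767). In the list of pancreatic and small-intestinal transcripts 1 of 10, Cela1, fell and 0 rose (1 when adjusted over the list alone; camera adjusted p = 0.945). The median, mean and test of a list differed in sign in 3 cases. The antimicrobial list had a median of -0.01, a mean of 0.53 and a downward test, the heat shock list a median of 0.11, a mean of -0.07 and a downward test, and the Elf4 target list a median of 0.19, a mean of 0.05 and a downward test. The sign of the antimicrobial median turned with the library left out. In limma it stood at 0.70 without wild type replicate 1 and -0.57 without wild type replicate 2.

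Camera called 20 of the 37 lists, 10 higher and 10 lower, while fry called 0 (15 lists at an unadjusted p under 0.05). With an estimated correlation 0 held (0 lists at an unadjusted p under 0.05), but that test had 2 residual degrees of freedom and could pass few lists. With 2 libraries a group an exact permutation test of a single gene cannot give a p below 0.333, and with limma 0 genes passed when any 1 library was left out (3778 to 6271 at an unadjusted p under 0.05). edgeR then called 1285 to 3754, the fewest without wild type replicate 2, followed by 2142 without Elf4fl/fl-Villin-Cre replicate 1. Genes counted in the lists that lost an edgeR call in at least 1 such fit also included Trpm5, Emcn, Lyve1, Pecam1, Lpl, Fabp4, Hba-a2, Aldoa, Eno1, Gsdmd, Casp8, Bax, Hspb8, Dnajb1 and Hspb1 (highest adjusted p of each, 0.0541 to 0.17). Of 119 named genes past the threshold, 19 moved by a fold of over 1.5 in limma without 1 library, 4 of them globin genes, and 0 changed sign. Lists that camera did not call in the planned test but did in a few others were the mast cell, pancreatic, mitochondrial and ribosomal lists, in 2 settings each, and the adipocyte list, in 1. The balance of calls moved with the scaling: 44.4% of called genes were higher with the deposited scaling, 28.7% with median scaling and 77.5% with library totals. Those scalings moved the median gene by -0.17 and 0.31 on the log2 scale, quantile scaling by -0.17, and 0 of the 3409 called genes changed sign under any of them. Called genes were selected on these same libraries, so the absence of sign changes says little about stability. Counts within lists moved as well. With quantile scaling and library totals, 3 and 7 goblet cell genes, 8 and 9 interferon-stimulated genes and 10 and 10 oxidative phosphorylation genes fell, while 5 and 8 ribosomal protein genes rose. Library totals gave 13 higher fibroblast, 9 endothelial, 9 enteric neuron, 6 T and NK cell, 4 B and plasma cell and 5 ETS or Elf4 target genes. Median scaling gave 3 lower proliferation, 3 smooth muscle, 3 unfolded protein, 6 hypoxia and 5 p53 genes, and quantile scaling 0, 0, 0, 1 and 1. Quantile scaling also left 0 T and NK cell genes higher. Medians below 0 turned above it for 9 lists under library totals. Of these the smooth muscle, p53, unfolded protein, mitochondrial and antimicrobial medians also did so with quantile scaling, and the heat shock median turned to -0.06 with median scaling.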

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

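The edgeR, DESeq2 and limma-voom fits, library totals, TMM scaling in limma, the minimum mean of 10 and the removal of GC and length trends were chosen after the data were seen; the other alternatives were planned. The 3409 calls became 3006 with a pseudocount of 0.1, 3254 without a filter, 2532 with quantile scaling, 3886 with median scaling, 4054 with edgeR, 4155 with DESeq2 and 4055 with limma-voom. In all fits 0 of the main calls changed sign, which says little about stability because the calls were selected on the same libraries. Library totals gave 5247 calls, 4069 higher and 1178 lower, since they raise the median gene by 0.31. An adjusted p of 0.01 left 362 genes, 182 higher and 180 lower, and a fold of at least 2 left 1947, 904 higher and 1043 lower.

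The replicate numbers share nothing in the labels and 2 pairs are too few to show a pairing (the replicate differences of the groups correlated at 0.104 across genes). With the number as a block limma called 4511 genes and edgeR 5433, 2456 higher and 2977 lower.

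Leaving out 1 library gave 0 calls with limma in all 4 cases, 0 higher and 0 lower, where 1 residual degree of freedom is left and a lone library is taken to vary like the other group. With edgeR it gave 1285 to 3754 calls, 476 to 1563 higher and 809 to 2191 lower. Of 119 named genes past the threshold, 86 were called by edgeR in all 4 such fits, and 28 were lost without wild type replicate 2. The log2 fold change of Elf4 ranged from -1.23 to -0.94 with limma, where it lost its call (adjusted p = 0.0911 to 0.226), and from -1.27 to -0.96 with edgeR, where it was called each time. With all libraries it was lowest in size under library totals, at -0.77.

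With an estimated correlation, and so on 2 residual degrees of freedom, camera called 0 lists, and fry 0. Among lists called, the smooth muscle median turned to 0.0437 with quantile scaling and 0.00762 with library totals, and the proliferation median to 0.09 with library totals. With all libraries neither limma nor edgeR called mt-Nd2 or mt-Nd6, but edgeR called mt-Nd6 without wild type replicate 2 (adjusted p = 0.0315). mt-Nd2 turned to -0.0366 with GC and length trends removed. Leaving out 1 library gave -0.0332 to 0.704 for mt-Nd2 and -0.00163 to 1.56 for mt-Nd6. Beyond these, 575 values of single genes and 46 of lists fell below the threshold under some setting and 18 and 41 passed it. The cause of these shifts was not tested. Depth limits genes such as Cma2 and Il17a, which had few or 0 reads in a group.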

Other observations

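The genes in this part were chosen after their values were seen, as were all tests of explanations here. Gene families defined by a shared symbol root added detail. Fisher's exact test, one-sided, was run for 326 families of at least 8 genes against all tested genes. It treats the genes of a family as independent, so its p-values do not measure the spread between samples. The background included genes with few reads, which were seldom called: 3349 of the 3409 calls lay among the 16881 genes with a mean value of at least 10. Families of well-expressed genes therefore get smaller p-values. Cox genes fell in 15 of 26 cases (adjusted p = 1.31e-07; 10 of 26 with quantile scaling and 7 with library totals) and Chmp genes, of the ESCRT-III membrane remodelling complex, in 9 of 10 (adjusted p = 3.82e-07; 2 of 10 with quantile scaling and 3 with library totals). Matrix remodelling families rose: 9 of 19 Mmp genes (adjusted p = 0.000175), 13 of 41 collagen genes (adjusted p = 0.000188; 20 with library totals) and 8 of 19 Adamts genes (adjusted p = 0.00121). Col7a1, the anchoring fibril collagen, rose by 2.49, Adamts4 by 2.46 and Thbs1 by 2.64 (limma adjusted p = 0.00737, 0.00973 and 0.00636). Il1rl1, the interleukin 33 receptor, rose by 4.59 ± 0.18 and Il33 by 1.73 (limma adjusted p = 0.00114 and 0.0303), and edgeR lost Il33 without wild type replicate 2 (adjusted p = 0.06). The transcription factor genes Cdx1 and Hnf4a fell by 1.83 and 1.78 and the inflammasome sensor gene Nlrp6 by 3.60 (limma adjusted p = 0.00961, 0.00986 and 0.00799).

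The gasdermin C and mucosal mast cell protease genes that fell are both known to respond to type 2 cytokines. Il4 had 14 and 18 reads in wild type and 31 and 27 in Elf4fl/fl-Villin-Cre colon. Its log2 fold change was 0.50 ± 0.38, and it was not called (limma adjusted p = 0.41). Il5 and Il13 were near the limit of detection, with 4 and 5 reads against 9 and 0, and 4 and 2 against 2 and 3. Among other mast cell genes, Cma1 and Tpsb2 had log2 fold changes of -0.01 ± 0.22 and -0.02 ± 0.64, and Mcpt4 of -0.68 ± 0.68 (limma adjusted p = 0.986, 0.989 and 0.534). Cpa3 had 124 and 61 reads in wild type and 30 and 97 in Elf4fl/fl-Villin-Cre colon (limma adjusted p = 0.311), so none of these was called. Pancreatic transcripts appeared almost only in Elf4fl/fl-Villin-Cre replicate 1. Prss2 had 427 reads there against 3 in replicate 2 and 1 and 0 in wild type, and Ctrb1 had 794 against 2 and 3 and 4.

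Absorptive, goblet cell and junction lists fell while neutrophil, macrophage, fibroblast, endothelial and neuronal lists rose, which a smaller epithelial share of the RNA could produce by itself. Such a shift would raise the other cell types alike, while the neutrophil median lay 2.64 above that of smooth muscle (17 and 15 genes, permutation p = 0.00076, two-sided). If all epithelial types were lost equally, their lists would also fall alike. The enteroendocrine median lay 2.11 above the absorptive one (14 and 21 genes, permutation p = 1e-05, the smallest 100000 permutations can give). Both pairs of lists were chosen after their medians were seen. The permutations treat the genes of a list as independent, while the estimated correlation was 0.84 in the smooth muscle list. These p-values do not measure the spread between samples, so neither comparison decides the cause. Another position of the piece along the colon stays open: posterior Hox genes (groups 9 to 13; 6 of 11 lower, 0 higher) had a median -0.82 from that of anterior ones (4 of 20 higher, 3 lower; permutation p = 0.0953). Erythroid genes had a median of 2.57 (1.84 and 3.39 without wild type replicate 1 and 2, respectively) beside 2.33 for neutrophil genes. More blood in the piece and greater epithelial injury in Elf4fl/fl-Villin-Cre mice were not tested. Both remain hypotheses beside a shift of composition.

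The fall of interferon-stimulated genes may reflect loss of epithelium, reduced interferon signalling, or both. Whether the scaling between libraries contributes to the fall was not decided. The other scalings moved the median gene by -0.17 (quantile and median), 0.31 (library totals) and -0.02 (TMM). The list need not follow the median gene: with quantile scaling its median went up, from -0.997 to -0.706. Under these scalings the list median stayed below 0, from -1.17 to -0.68 (95% bootstrap interval over genes under library totals, -0.87 to -0.47). That interval covers the spread between genes of the list and not between libraries. With quantile scaling 8 members passed and with library totals 9, against 16. A smaller epithelial share cannot be told apart, because the interferon median lay only 0.29 above the junction median (25 and 23 genes, permutation p = 0.147). Other epithelial lists would give another reference, with medians of -1.57 (absorptive), -1.14 (goblet cell) and 0.55 (enteroendocrine). No purified epithelium was analysed here.

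The lower Elf4 level could come from the deletion, from a smaller epithelial share, or from both. Elf4 lay 0.20 above the median of the epithelial junction genes on the log2 scale, so its fall did not exceed that of the median junction gene. The comparison depends on the epithelial list taken, as the medians were -1.57 for absorptive, -1.14 for goblet cell and 0.55 for enteroendocrine genes. The explanations cannot be told apart with counts per gene, which do not separate the deleted exons from the rest.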
